A study of Mus musculus with 15 samples.

How the data were processed

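Liver RNA of mice that carried luciferase or LbNOX and received water or ethanol by gavage was sequenced in 15 libraries, prepared with a KAPA mRNA kit per the labels' protocols. The design text of the series speaks of wild-type or ChREBP animals, while the sample titles and the table header name luciferase and LbNOX. The titles and header were followed, and the genotype of the animals with respect to ChREBP is not settled here. The submitters' processing notes name Salmon 1.5.1, DESeq2 1.30.1 and the mm10 genome, without saying which step each served. The deposited table holds a signal per gene and library, normalized counts in which every library was divided by its own factor before the table was deposited. The columns carry a group and a library name from M1 to M15, and no replicate number. All columns were used, and the groups were taken from the table's header.

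The factor of each library was read from the smallest step between its values. All 244950 values then lay within 0.001 of whole reads (100%), so reads were recovered by division; the factors ran from 0.723 to 1.67. Recovered depth was 14.5 to 23.7 M reads in luciferase water, 13.7 to 20.6 M in LbNOX water, 12.2 to 14.4 M in luciferase ethanol and 10.6 to 15.7 M in LbNOX ethanol libraries. The 10 most abundant genes took 10.8% to 14.5% of each library, and 823 to 1466 genes were at 0. Date-like names, as left by spreadsheet software, were given to 23 genes; these are not named. Replicate pairs had r of 0.919 to 0.961 across genes, with a chi-square per degree of freedom of 26.4 to 145, and no pair was duplicated. Median SD within groups on the log2 scale was 0.324, 0.285, 0.231 and 0.248 for luciferase water, LbNOX water, luciferase ethanol and LbNOX ethanol.

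The test was limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust variances, on log2 of the normalized count plus 1, for genes at 10 or more in at least 3 libraries. The plan written before the data were examined set edgeR for counts and this test for normalized values. A single fit held the 4 groups and gave 5 contrasts: ethanol against water in each construct, LbNOX against luciferase after each gavage, and the difference of the ethanol effects. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors are those of limma. Genes were placed with GENCODE vM21 on GRCm38.

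Lists of genes were fixed before the data were examined: 24 of responses, 12 of cell markers and 2 of quality, 38 in all. They were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a set moves in a single direction on balance and does not compare it with other genes. List p-values were adjusted over the lists of a comparison. Genes named are the 8 largest rises and 8 largest falls among called genes with a mean of 100 or more, up to 4 members of each list described by smallest p, 13 genes of ethanol and carbohydrate metabolism in every comparison, and the 3 smallest p-values where none passed. Some genes that this rule chose are not reported here.

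Alternatives set beforehand were quantile normalization, no trend, other filters and pseudocounts, a fit of only the groups compared, and each library left out. Added after the values were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the omission of M3 and M8, and the omission of genes at 0 in any library where the median of the others was at least 100. On recovered reads edgeR called 1046, 1, 0, 755 and 217 genes in the order luciferase ethanol, LbNOX ethanol, LbNOX after water, LbNOX after ethanol and difference.

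The test was tried on simulated data in which 200 genes with a mean of 100 or more were changed. A further 16 such genes were raised by 1 on the log2 scale as a list. Among genes changed 2-fold, 73.1% were recovered in the luciferase ethanol design, 64.2% in the LbNOX ethanol design, 74.6% for LbNOX after water and 50.7% after ethanol; at 1.5-fold the shares were 20.9%, 14.9%, 32.8% and 10.4%, and at 4-fold 97.0%, 93.9%, 93.9% and 93.9%. Of the calls made there, 9.80%, 6.77%, 3.38% and 1.75% were false. Counts were drawn independently for each gene and library, so no library stood apart across many genes. The shares therefore do not cover genes with a lower mean or libraries that stand apart. The difference of the ethanol effects was not simulated. Transcripts of the constructs were not analysed here.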

Results

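The data were RNA-seq of 15 mouse liver libraries in 4 groups. The livers expressed either luciferase, a light-producing enzyme that served as the control construct, or LbNOX, a bacterial oxidase that turns NADH into NAD+ while making water. Water or ethanol was given by gavage, and the liver was collected 6 h later. The luciferase groups held 5 libraries after water (M1 to M5) and 3 after ethanol (M10 to M12), and the LbNOX groups held 4 after water (M6 to M9) and 3 after ethanol (M13 to M15). The depth recovered from the table was 10.6 to 23.7 M reads per library, with 12.2 to 14.4 M in the luciferase ethanol libraries and 10.6 to 15.7 M in the LbNOX ethanol libraries. Of 16330 genes listed, 13570 were tested. The labels do not state that the libraries came from separate animals, so the p-values measure the spread between these samples. The design asks how the response of the liver to ethanol differs when LbNOX is present. Levels are given as normalized counts, mean ± SD over the libraries of a group.

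In luciferase livers, G6pc and genes of fatty acid synthesis such as Acly rose after ethanol, and genes induced by interferon such as Cxcl10 fell; as lists, lipogenesis had an adjusted p = 0.172 with an estimated correlation and interferon response an adjusted p = 0.417 with an estimated correlation. G6pc, the catalytic subunit of glucose-6-phosphatase, rose from 3424 ± 1442 normalized counts after water (n = 5) to 37891 ± 15043 after ethanol (n = 3), a log2 fold change of 3.57 (SE 0.46, adjusted p = 0.000367). Acly, which makes cytosolic acetyl-CoA from citrate, rose from 3558 ± 380 to 24197 ± 9275 (2.70, SE 0.22, adjusted p = 2.1e-05), and Pklr, the liver pyruvate kinase, rose from 2994 ± 1467 to 12038 ± 4398 (2.10, SE 0.41, adjusted p = 0.00569). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 2241 ± 833 to 442 ± 151 (−2.32, SE 0.32, adjusted p = 0.000512). Cxcl10, an interferon-induced chemokine, fell from 738 ± 305 to 137 ± 83.6 (−2.50, SE 0.40, adjusted p = 0.00168). The smallest p-value belonged to Ttc25, a gene of motile cilia, which rose from 57.5 ± 14.4 to 1334 ± 125 (4.54, SE 0.27, adjusted p = 7.6e-07).

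**Figure D1:**
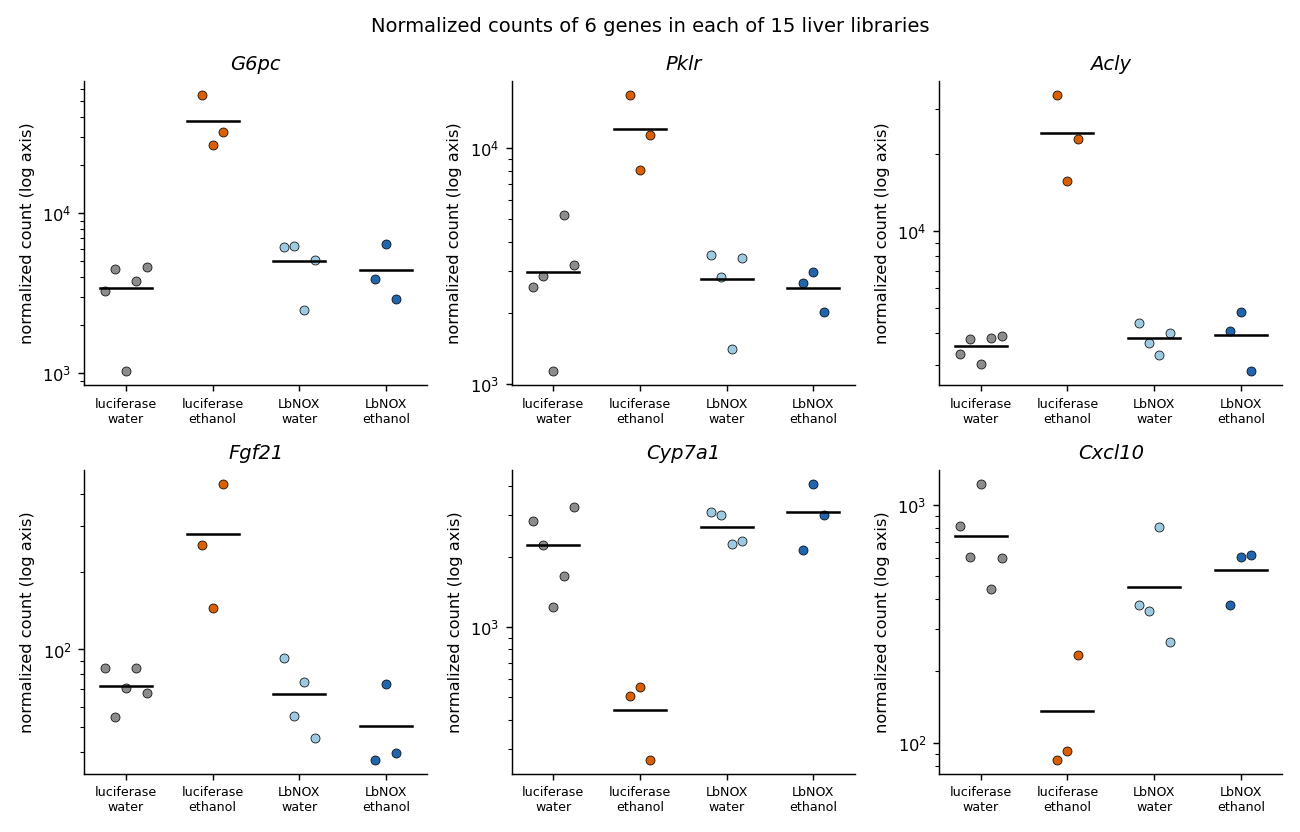
Normalized counts (log axis) of G6pc, Pklr, Acly, Fgf21, Cyp7a1 and Cxcl10 in each library of the 4 groups; each point is a library and each line is the mean of its group. The luciferase ethanol libraries stand apart: the group mean of G6pc was 37891 there and 4408 in the LbNOX ethanol libraries.

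The largest rises in luciferase livers after ethanol included genes that were barely detected after water. Adcy10, the soluble adenylyl cyclase, had 4.40 ± 3.18 normalized counts after water and 526 ± 216 after ethanol. Col9a3, a collagen chain, went from 3.10 ± 2.41 to 318 ± 125, and Sorcs2, a sorting receptor, from 9.71 ± 3.86 to 533 ± 301; all 3 passed the test. Slc34a2, a phosphate transporter, rose from 27.0 ± 17.0 to 810 ± 794. Slc2a4, the insulin-responsive glucose transporter, rose from 76.4 ± 37.4 to 1349 ± 356 (log2 fold change 4.26), and Plcxd1 rose from 39.5 ± 11.1 to 491 ± 212 (3.56). Among the largest falls, Acot3, an acyl-CoA thioesterase, went from 973 ± 622 to 106 ± 35.2 (−2.98). Gbp11, an interferon-inducible gene of the guanylate-binding protein family that is annotated as a polymorphic pseudogene, went from 168 ± 39.4 to 30.1 ± 12.5 (−2.51).

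Targets of ChREBP, the sugar-responsive transcription factor encoded by Mlxipl, rose together in luciferase livers after ethanol. Of 16 tested, 15 rose over all genes and 16 when adjusted over the list alone, with a median log2 fold change of 1.52 (camera adjusted p = 6.79e-16; adjusted p = 0.172 with an estimated correlation). Mlxipl itself rose (1.48, adjusted p = 0.00448), as did the transcription factor Klf10 (2.16), the hormone gene Fgf21 (1.81), glycerol-3-phosphate dehydrogenase Gpd1 (1.48) and the arrestin-like Arrdc4 (adjusted p = 0.00298). Txnip, an inhibitor of glucose uptake, did not pass over all genes (0.88, adjusted p = 0.0634). Of 18 genes of de novo lipogenesis, 13 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 1.04e-10; adjusted p = 0.172 with an estimated correlation). Those that rose included Elovl6, a fatty acid elongase (2.62), Fasn, fatty acid synthase (2.34), and Acaca, acetyl-CoA carboxylase (1.67). The gene of this list that fell was the desaturase Fads2 (−0.84), named after its values were seen.

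Other lists of carbon metabolism showed smaller medians in luciferase livers. Of 15 glycolysis genes, 4 rose (4 adjusted over the list alone), among them Pfkfb3, which makes the activator of phosphofructokinase (1.79), and Gpi1, glucose-6-phosphate isomerase (1.41). The glycolysis median was 0.09 (camera adjusted p = 0.0101; adjusted p = 0.433 with an estimated correlation). Of 13 redox shuttle genes, 4 rose (4 over the list alone; median 0.36, camera adjusted p = 0.00499; adjusted p = 0.419 with an estimated correlation), including Gpd1, its mitochondrial partner Gpd2 (0.98) and the aspartate aminotransferase Got1 (1.27). Of 17 gluconeogenesis and amino acid catabolism genes, 3 rose (5 over the list alone): G6pc, Got1 and Tat, tyrosine aminotransferase (1.10; adjusted p = 0.110 without M11). That median was 0.25 (camera adjusted p = 0.00276; adjusted p = 0.616 with an estimated correlation). Of 24 cholesterol synthesis genes, 1 rose and 5 fell (3 and 9 over the list alone), with Insig1, a brake on sterol synthesis, at −0.96, the synthase gene Hmgcs1 at −0.74 and the sterol carrier Stard4 at 1.05. The cholesterol median was −0.17 (camera adjusted p = 0.0429; adjusted p = 0.711 with an estimated correlation). Of 26 fatty acid oxidation genes, 4 fell (5 over the list alone), among them the thioesterase Acot2 (−1.69), with a median of −0.20 (camera adjusted p = 0.0182; adjusted p = 0.775 with an estimated correlation). Ldha, lactate dehydrogenase (0.23, adjusted p = 0.464), and Cyp2e1, the ethanol-oxidising cytochrome (0.24, adjusted p = 0.820), did not pass. The camera call of the cholesterol list ended without M3 (adjusted p = 0.111), M4 (0.0920), M5 (0.0612) or M11 (0.574), and that of the fatty acid oxidation list without M4 (0.127), M5 (0.0599), M10 (0.0974) or M12 (0.143). The glycolysis median was 0.01 with quantile normalization and 0.24 without M3. Gckr, which encodes a regulator of sugar metabolism, was listed at 0 in 8 libraries of all groups, and was 176, 136 and 186 in M1, M3 and M5, 28.8 in M6, 61.8 and 42.4 in M11 and M12, and 37.4 in M13.

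Hormone and stress lists also moved in luciferase livers. Of 15 glucocorticoid-response genes, 5 rose (10 over the list alone), with a median of 0.91 (camera adjusted p = 2.36e-06; adjusted p = 0.229 with an estimated correlation). They included Igfbp1, a secreted binder of insulin-like growth factors (2.22), and Dusp1, a phosphatase of MAP kinases (1.93). Of 20 genes of the integrated stress response, 3 rose and 1 fell (4 and 1 over the list alone; median 0.49, camera adjusted p = 0.000447; adjusted p = 0.172 with an estimated correlation). The pseudokinase gene Trib3 rose by 1.91 on the log2 scale and Chac1, which degrades glutathione, by 1.59. The gene that fell was the transcription factor Atf3, listed at 0 in M10 and M11 and at 23.7 in M12, against 46.4 to 134 after water; its call ended without M1, M3, M10 or M11 (adjusted p up to 0.162). Of 16 unfolded protein response genes, 3 fell (5 over the list alone), among them the secreted factor Manf (−0.81), with a median of −0.29 (camera adjusted p = 0.000265; adjusted p = 0.172 with an estimated correlation). Of 13 heat shock genes, 4 fell (5 over the list alone; median −0.31, camera adjusted p = 0.00113; adjusted p = 0.417 with an estimated correlation). Of 19 NRF2 oxidative stress genes, 2 fell (4 over the list alone; median −0.48, camera adjusted p = 0.000371; adjusted p = 0.433 with an estimated correlation). Of 18 proliferation genes, 4 fell and 1 rose (11 and 1 over the list alone), with a median of −0.76 (camera adjusted p = 8.95e-06; adjusted p = 0.419 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell (−1.20), and Rrm2, a ribonucleotide reductase subunit, rose (1.03).

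Interferon-response genes were lower in luciferase livers after ethanol. Of 19 tested, 10 fell (12 adjusted over the list alone), with a median of −1.47 (camera adjusted p = 1.7e-08; adjusted p = 0.417 with an estimated correlation). They included Cxcl10, the signalling gene Stat2 (−0.89) and Ifit1, which binds viral RNA (−2.52, adjusted p = 0.0165). Tgtp1, an interferon-inducible GTPase outside the list, fell too (−2.53, adjusted p = 0.0108); without M10 the adjusted p was 0.107 for Ifit1 and 0.0716 for Tgtp1. Of 12 MHC class II and interferon-gamma genes, 3 fell (10 over the list alone), including the guanylate-binding gene Gbp3 (−1.80) and the transcription factor Irf1 (−0.98), with a median of −0.93 (camera adjusted p = 1.4e-06; adjusted p = 0.417 with an estimated correlation). Markers of T and NK cells had a median of −1.0 (camera adjusted p = 0.000165; adjusted p = 0.417 with an estimated correlation) and those of Kupffer cells −0.46 (camera adjusted p = 0.0147; adjusted p = 0.616 with an estimated correlation; camera adjusted p = 0.0604 without M3 and 0.0519 without M10). The interferon list was highest in the water library M4, and its median was −1.14 without it.

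Other lists had 0 or few members called in luciferase livers and were not called by camera. The medians were −0.13 for ethanol and acetate metabolism (camera adjusted p = 0.460), 0.13 for NAD metabolism (0.519), −0.20 for p53 targets (0.264), 0.30 for clock genes (0.231), 0.38 for immediate early genes (0.397), 0.06 for xenobiotic genes (0.483) and 0.04 for oxidative phosphorylation (0.483). Acute phase genes had a median of 0.11 and bile acid genes had 0.05, while camera placed both lower (0.976 and 0.915). Among cell markers the medians were 0.10 for hepatocytes (0.499), 0.13 for pericentral (0.483) and 0.18 for periportal hepatocytes (0.397), −0.39 for endothelial cells (0.231), 0.29 for neutrophils (0.667), −0.36 for B and plasma cells (0.527), 0.60 for cholangiocytes (0.0911), −0.40 for red blood cells (0.0583) and 0.50 for pancreas and fat (0.673). Stellate cell markers had a median of −0.01 with camera placing them higher (0.976). Genes of the mitochondrial genome stood at 0.15 (0.352) and ribosomal protein genes at 0.04 (0.465).

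In all, 1052 genes passed the test in luciferase livers, 627 higher and 425 lower after ethanol, and 485 of them changed by more than 2-fold (limma). The count was 467 without M10 and 636 without M12, 611 when only the luciferase groups were fitted, and 1646 by DESeq2 on the recovered reads. Of 59 called genes chosen for naming, 41 kept the call whichever library was left out.

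In LbNOX livers, G6pc, Acly and Pklr had similar mean levels after water and ethanol. G6pc had 5000 ± 1741 normalized counts after water (n = 4) and 4408 ± 1817 after ethanol (n = 3; log2 fold change −0.17, SE 0.48, adjusted p = 0.917). Acly had 3816 ± 480 and 3912 ± 1012 (0.01, SE 0.23, adjusted p = 0.989), and Pklr had 2796 ± 974 and 2559 ± 497 (−0.06, SE 0.43, adjusted p = 0.968). The values were 0.06 for Fasn, 0.05 for Mlxipl, 0.06 for Gpd1, −0.42 for Fgf21 and −0.35 for Txnip, none of which passed. The gene that passed was Tarsl2, a threonyl-tRNA synthetase-like gene, which fell from 442 ± 64.9 to 199 ± 10.2 (−1.14, SE 0.15, adjusted p = 0.0287). Its call ended with any of 9 libraries left out, with an adjusted p up to 0.166, without M6, and without the trend (adjusted p = 0.0607). Gdf15, a stress-induced hormone, had 285 ± 46.0 after water and 442 ± 98.8 after ethanol (0.62, adjusted p = 0.276).

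Some list medians in LbNOX livers were called by camera after ethanol, none of them with an estimated correlation, where the adjusted p = 0.898 was the smallest. The ChREBP list had a median of −0.24 (camera adjusted p = 0.0650) and the lipogenesis list −0.07 (camera adjusted p = 0.510), with 0 members called in either. Fatty acid oxidation genes were lower (median −0.30, camera adjusted p = 0.000696), as were genes of oxidative phosphorylation (−0.18, camera adjusted p = 0.0106), proliferation (−0.34, camera adjusted p = 0.00339) and ribosomal proteins (−0.22, camera adjusted p = 0.000152). Lists of p53 targets (0.32, camera adjusted p = 0.00339), heat shock genes (0.25, camera adjusted p = 0.0198) and immediate early genes (0.30, camera adjusted p = 0.0336) were higher. Neutrophil markers had a median of 1.96 (camera adjusted p = 0.000696), with 0 of 7 members called over all genes and 3 adjusted over the list alone; S100a8, a calcium-binding protein of neutrophils, was at 2.83 (adjusted p = 0.257). Calls of lists ended without M9 for oxidative phosphorylation (median −0.08, camera adjusted p = 0.328), ribosomal proteins (−0.10, 0.0763), heat shock (0.16, 0.0884) and immediate early genes (0.28, 0.0884). Without M15 the oxidative phosphorylation median was −0.07 (0.415) and the proliferation median −0.64. Without M13 calls ended for heat shock (0.0904), p53 targets (0.0589) and immediate early genes (0.363), and the neutrophil median was 1.19 (0.0332). The neutrophil level stood highest in M13 (2.61 as a median of centred log2 values), against −0.08 in M14, 0.87 in M15 and 0.84 in the water library M8.

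By limma, 1 gene passed in LbNOX livers and 1571 had an unadjusted p under 0.05. The counts were 1 by edgeR and 291 by DESeq2 on the recovered reads, 116 without M3 and M8 and 28 without M14, so the number of genes that respond to ethanol in LbNOX livers was not settled. The 627 genes that rose in luciferase livers had a median log2 fold change of 1.0 there and 0.05 in LbNOX livers, and the 425 that fell had −0.89 and −0.12. In LbNOX livers 56.8% of the risen genes were above 0 and 63.1% of the fallen genes were below 0, while 49.5% of all genes were above 0. No gene passed in both constructs by limma; 71 did in one direction by DESeq2 and 24 without M3 and M8. Across all genes tested, which are not independent replicates, the ethanol effects of the constructs had r = 0.0526 and rho = 0.0692; these comparisons share no library.

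**Figure D2:**
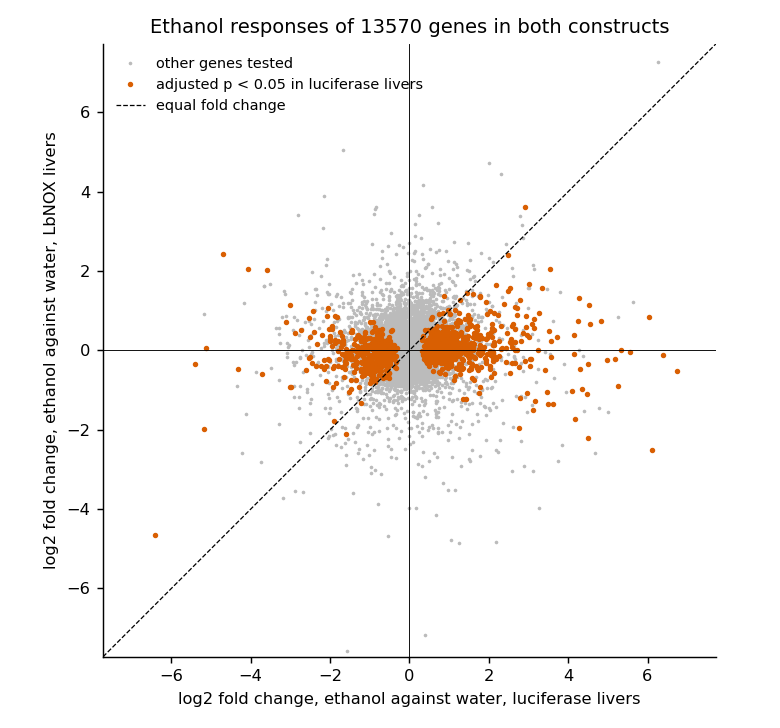
Log2 fold change after ethanol of the 13570 genes tested, in luciferase livers (x axis) and in LbNOX livers (y axis); each point is a gene, orange for the 1052 genes that passed in luciferase livers, and the dashed line marks equal fold changes. The orange points lie along the x axis, with medians of 1.0 and 0.05 on the x and y axes for the genes that rose.

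**Figure D3:**
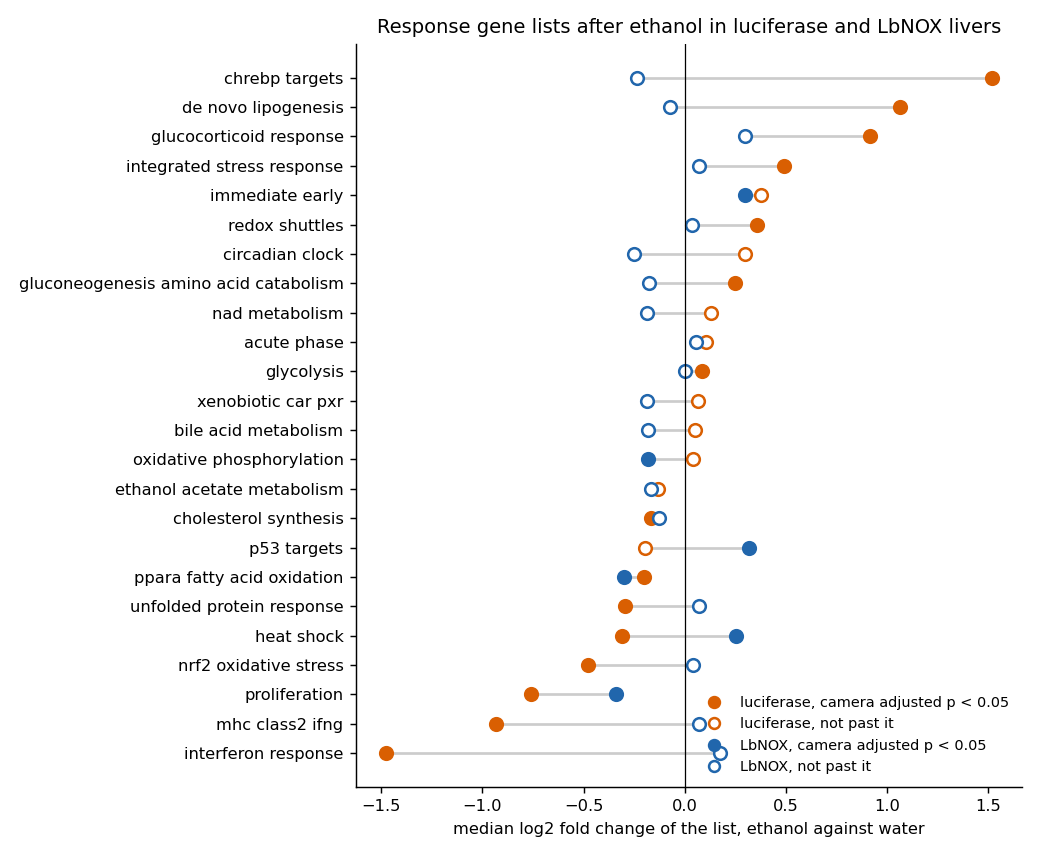
Median log2 fold change after ethanol of 24 response lists in luciferase livers (orange) and LbNOX livers (blue), filled where camera with its preset correlation gave an adjusted p below 0.05. With an estimated correlation 0 lists were called (smallest adjusted p 0.172 and 0.898); the ChREBP list lies at 1.52 in luciferase livers and at −0.24 in LbNOX livers.

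The difference of the ethanol effect between the constructs was tested directly. The ethanol effect was lower in LbNOX livers than in luciferase livers for G6pc, Acly and Ttc25, and higher for Cyp7a1 and Cxcl10. The difference was −3.74 for G6pc (SE 0.67, adjusted p = 0.0130), −2.69 for Acly (SE 0.32, adjusted p = 0.00200) and −3.87 for Ttc25 (SE 0.39, adjusted p = 0.00103). It was 2.49 for Cyp7a1 (SE 0.46, adjusted p = 0.0159) and 2.82 for Cxcl10 (SE 0.58, adjusted p = 0.0281). Other genes with a large difference were Slc2a4 (−3.52), Tha1, a threonine aldolase (−3.44), Plcxd1 (−3.33) and Thrsp, a regulator of lipogenesis (−3.24). On the other side stood Tgtp1 (3.34), the deubiquitinase Usp20 (2.65), Gbp11 (2.34), Cd274, which encodes the ligand PD-L1 (2.23), and Gbp10 (2.14). For Gbp10 part of this lay in the water groups, where it stood at −1.41 in LbNOX against luciferase livers (limma adjusted p = 0.512). Pklr (−2.16, adjusted p = 0.0870), Fasn (−2.29, adjusted p = 0.0847), Mlxipl (−1.43, adjusted p = 0.0937), Gpd1 (−1.42, adjusted p = 0.0560) and Txnip (−1.23, adjusted p = 0.144) did not pass the test of the difference.

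By list, 8 of 16 ChREBP targets differed between the constructs over all genes and 16 adjusted over the list alone, with a median difference of −1.74 (camera adjusted p = 1.41e-16; adjusted p = 0.304 with an estimated correlation). They included Klf10 (−2.32), Fgf21 (−2.23), the lipase-like Pnpla3 (−3.12) and Agpat2, an enzyme of triglyceride synthesis (−1.29). Of 18 lipogenesis genes, 5 differed (13 over the list alone; median −1.20, camera adjusted p = 9.37e-11; adjusted p = 0.304 with an estimated correlation), among them Elovl6 (−1.95) and Mid1ip1, which promotes acetyl-CoA carboxylase activity (−2.27). Of 19 interferon-response genes, 2 differed, namely Cxcl10 and Stat2 (1.06), and 7 did over the list alone. Their median was 1.51 (camera adjusted p = 1.31e-07, and adjusted p = 0.568 with an estimated correlation). Part of this lay in the water groups, where this list and the MHC class II list had lower medians in LbNOX livers. For 12 MHC class II and interferon-gamma genes the median was 1.13 with 1 called, Irf1 (1.29), and 6 over the list alone (camera adjusted p = 1.77e-05; adjusted p = 0.568 with an estimated correlation). Heat shock genes had a median of 0.63 with 0 called and 4 over the list alone (camera adjusted p = 9.63e-06; adjusted p = 0.304 with an estimated correlation). Marker medians differed as well, at 0.99 for T and NK cells, 0.61 for Kupffer cells and 1.4 for neutrophils (camera adjusted p = 0.0182, 0.0141 and 0.0297; adjusted p = 0.568 with an estimated correlation for each), and the hepatocyte markers stood at −0.45 (camera adjusted p = 0.0634). Without M15 the medians were 0.57 for T and NK cells (camera adjusted p = 0.155) and 0.39 for Kupffer cells (0.136), and without M13 the neutrophil median was 0.75 (0.189).

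In all, 227 genes passed the test of the difference, 58 positive and 169 negative (limma). The count was 644 by DESeq2 on the recovered reads, 382 without M3 and M8, 151 without the mean-variance trend, and 402 without M8; it was 70 without M15, 71 without M10, 86 without M6, 93 without M12, 94 without M7, 110 without M13, 128 without M9 and 144 without M1. Of 29 called genes chosen for naming, 10 kept the call whichever library was left out, among them Acly, Ttc25, Tha1, Plcxd1, Klf10 and Gbp10; the calls of Tgtp1, Thrsp and Fgf21 ended in most of these fits, with adjusted p up to 0.134, 0.132 and 0.111, each without M15. Without M10 the adjusted p was 0.0525 for G6pc, 0.0928 for Cxcl10 and Cd274, 0.0915 for Slc2a4 and Irf1, 0.116 for Pnpla3, 0.117 for Agpat2 and 0.122 for Stat2. Without M15 it was 0.0520 for Cyp7a1, 0.0788 for Usp20, 0.0734 for Elovl6 and 0.0630 for Mid1ip1, and without M6 it was 0.0511 for Gbp11.

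Between the constructs after water, no gene passed by limma (440 had an unadjusted p under 0.05), 0 by edgeR and 19 by DESeq2 on the recovered reads. The smallest p-values belonged to interferon-inducible GTPase genes. Gbp10 had 1440 ± 278 normalized counts in luciferase livers (n = 5) and 540 ± 111 in LbNOX livers (n = 4; log2 fold change −1.41, SE 0.24, adjusted p = 0.512; adjusted p = 0.0444 without M10). Ifi47 was at −1.01 and Iigp1 at −0.91 (adjusted p = 0.681 for each). The interferon-response list had a median of −0.81 with 0 called and 1 over the list alone (camera adjusted p = 4.84e-14; adjusted p = 0.343 with an estimated correlation), and the MHC class II list had −0.74 with 0 called and 4 over the list alone (camera adjusted p = 1.07e-11; adjusted p = 0.343 with an estimated correlation). Without M4, where the interferon level was 1.85 against −0.17 to 0.79 in the other luciferase water libraries, the interferon median was −0.47. The MHC class II level was highest in M3 (1.27) and M1 (0.995) and was −0.41 in M4. T and NK cell markers stood at −0.31 (camera adjusted p = 0.0343; adjusted p = 0.757 with an estimated correlation), and at −0.10 without M3 (camera adjusted p = 0.568). The unfolded protein response list was lower in LbNOX livers, with a median of −0.22, 0 called and 2 over the list alone (camera adjusted p = 9.59e-09; adjusted p = 0.0489 with an estimated correlation). Its members included Manf (−0.47) and the chaperone gene Hspa5 (−0.42), neither called.

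Camera called 13 lists in this comparison, 1 with an estimated correlation, and 8 without M3. The xenobiotic, bile acid and periportal lists were among those that lost the call in both settings (camera adjusted p = 0.0556, 0.149 and 0.271 without M3). Not all of the lists called are named here. Xenobiotic genes stood at 0.32 (camera adjusted p = 9.12e-05; adjusted p = 0.757 with an estimated correlation), with Cyp3a11, a drug-oxidising cytochrome, at 0.34. Bile acid genes stood at 0.26 (camera adjusted p = 0.00394; adjusted p = 0.757 with an estimated correlation) and periportal hepatocyte markers at 0.21 (camera adjusted p = 0.0252; adjusted p = 0.757 with an estimated correlation). The ChREBP list was not called by camera (0.11, camera adjusted p = 0.424), with G6pc at 0.63, Pklr at −0.03 and Gpd1 at 0.06, none called.

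Between the constructs after ethanol, 822 genes passed, 304 higher and 518 lower in LbNOX livers (limma); this comparison uses the luciferase ethanol libraries again and is not independent of the ethanol effect in luciferase livers. Cyp7a1 was higher in LbNOX livers, at 3092 ± 984 normalized counts (n = 3) against 442 ± 151 (n = 3), a log2 fold change of 2.82 (SE 0.35, adjusted p = 0.000629). G6pc (−3.11, adjusted p = 0.0036), Acly (−2.59, adjusted p = 9.58e-05), Pklr (−2.19, adjusted p = 0.0129) and Fgf21 (−2.37, adjusted p = 0.00296) were lower. Usp20 (2.61), Cxcl10 (2.08), the acute phase gene Saa3 (1.95) and the transcription factor Klf6 (2.02) were higher, as were Disp2 (3.91) and Map2, a microtubule-associated protein (3.63). Among the largest falls, Hhipl1 went from 264 ± 111 to 16.3 ± 8.06 (−3.93) and Rgs16, a regulator of G-protein signalling, from 6430 ± 661 to 645 ± 554 (−3.78). Nfe2l3, a transcription factor, was at 201 ± 135 in luciferase and 4.44 ± 2.65 in LbNOX ethanol libraries, and Sorcs2 was at 533 ± 301 and 4.22 ± 4.05. Adpgk, an ADP-dependent sugar kinase, also passed but was listed at 0 in M13 and M14 and at 133 in M15, against 160 to 230 in luciferase ethanol libraries.

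Of the 16 ChREBP targets, 14 were lower in LbNOX livers after ethanol (16 adjusted over the list alone; median −1.70, camera adjusted p = 1.22e-16; adjusted p = 0.275 with an estimated correlation), and of 18 lipogenesis genes 11 were lower (15 over the list alone; median −1.14, camera adjusted p = 1.11e-11; adjusted p = 0.275 with an estimated correlation), including Srebf1, the sterol-regulatory transcription factor (−1.15). Of 13 heat shock genes, 2 were higher, Hsp90aa1 (0.82) and Hspb1 (1.06), and 7 over the list alone (median 0.54, camera adjusted p = 0.000208; adjusted p = 0.536 with an estimated correlation). Kupffer cell markers stood at 0.51 and hepatocyte markers at −0.36 (camera adjusted p = 0.0377 for each; adjusted p = 0.778 with an estimated correlation), and ribosomal protein genes at −0.31 (camera adjusted p = 2.21e-06; adjusted p = 0.778 with an estimated correlation). The Kupffer level was 0.55 in M15, against −0.10 in M13 and −0.27 in M14, and the median was 0.22 without M15 (camera adjusted p = 0.345). The hepatocyte call ended with quantile normalization (0.306) and without M10 (0.115), M11 (0.127) or M13 (0.114). The count of genes was 1365 by DESeq2 on the recovered reads, 316 without M10, 320 without M15, 355 without M12 and 400 without M13. Calls also ended without M10 for Saa3 (adjusted p = 0.0945), Cxcl10 (0.0758) and Pklr (0.0668), without M13 for Klf6 (0.0846), Hsp90aa1 (0.161), Hspb1 (0.127) and Adpgk (0.146), and without M15 for Disp2 (0.0845), Map2 (0.110) and Rgs16 (0.0938). For Adpgk, at −5.24 by limma, edgeR gave −2.13 (adjusted p = 0.308) and DESeq2 −2.14 (adjusted p = 0.373).

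Genes lie, in GRCm38 coordinates, as follows. Acly is on chromosome 11 at 100476353 to 100528000 on the minus strand and Ttc25 on chromosome 11 at 100545607 to 100572568 on the plus strand, so that 17.6 kb separate their facing ends. G6pc is on chromosome 11 at 101367561 to 101377903, Pklr on chromosome 3 at 89136142 to 89146784, Fgf21 on chromosome 7 at 45613886 to 45615490, Cyp7a1 on chromosome 4 at 6265612 to 6275633, Cxcl10 on chromosome 5 at 92346638 to 92348889, Mlxipl on chromosome 5 at 135089890 to 135138382, Tarsl2 on chromosome 7 at 65644898 to 65692091 and Gbp10 on chromosome 5 at 105215699 to 105239533. All of these are annotated as protein-coding genes. The values are given per gene symbol, with no division into exons or untranslated regions. How transcripts were combined into the value of a gene is not given in the sources used here. Annotated protein-coding genes on the same strand overlap Tgtp1, Gbp10, Acot3, Ifi47, Manf and Tarsl2, and genes on the opposite strand overlap Cxcl10, Pklr, Plcxd1, Sorcs2, Col9a3, Dbp, Dusp1, Agpat2, Acaca, Adpgk, Irf1, Srebf1 and Cdc20, as well as Manf and Tgtp1. How shared reads were divided, and whether strand was used, is not given in the sources used here, so the values of these genes are uncertain to that extent, as are those of close relatives such as the Gbp and Tgtp genes.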

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

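Among the tests in this part, the interferon tests and the hepatocyte test were chosen after results were seen. The others were set before, though the rule for cell shares came to include the hepatocyte test. The difference of the ethanol effect between the constructs was called for 227 genes. The genes named among them with a negative difference were Adcy10 (−7.27), Sorcs2 (−5.59), Ttc25 (−3.87), G6pc (−3.74), Slc2a4 (−3.52), Tha1 (−3.44), Plcxd1 (−3.33), Thrsp (−3.24), Pnpla3 (−3.12), Acly (−2.69), Klf10 (−2.32), Mid1ip1 (−2.27), Fgf21 (−2.23), Trib3 (−2.09), Elovl6 (−1.95), Hlf (−1.58), Gpi1 (−1.41), Rrm2 (−1.32), Stard4 (−1.32) and Agpat2 (−1.29). Of these, Stard4 kept the call in 3 of 15 fits with a library left out (adjusted p up to 0.122, M12), Rrm2 in 7 (up to 0.109, M15) and Gpi1 in 13 (up to 0.0586, M15). Those with a positive difference were Stat2 (1.06), Irf1 (1.29), Gbp10 (2.14), Cd274 (2.23), Gbp11 (2.34), Cyp7a1 (2.49), Usp20 (2.65), Cxcl10 (2.82) and Tgtp1 (3.34).

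Lists called by camera for this difference had medians of −1.74 (ChREBP targets), −1.20 (lipogenesis), −0.56 (gluconeogenesis), −0.49 (glucocorticoid response), −0.39 (clock), −0.36 (integrated stress response), −0.27 (oxidative phosphorylation), −0.25 (ribosomal proteins), −0.23 (redox shuttles), −0.0941 (glycolysis), 0.32 (unfolded protein response), 0.55 (NRF2), 0.60 (p53 targets), 0.61 (Kupffer cells), 0.63 (heat shock), 0.99 (T and NK cells), 1.13 (MHC class II), 1.4 (neutrophils) and 1.51 (interferon response). With an estimated correlation 0 of them were called. With camera, calls ended without M15 for clock (adjusted p = 0.161), integrated stress response (0.0749), oxidative phosphorylation (0.209), redox shuttles (0.0715) and glycolysis (0.0822), without M10 for NRF2 (0.0564) and without M11 for glucocorticoid response (0.0514). With quantile normalization the glycolysis median was 0.10 (0.387).

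The libraries were also regrouped in other ways. In luciferase livers, of 56 splits only 1, the real grouping, called as many as 1052 genes, and no other called more than 1. For the difference, gavage labels were reassigned within each construct. Of 100 assignments only 1, the real one, reached 227, the highest other being 139. Such reassignment breaks the ethanol effect of both constructs, so it cannot test whether their ethanol effects were equal. In LbNOX livers 13 of 35 splits called at least as many genes as the real grouping, which called 1, the highest being 10. Chance is not excluded there, but a count of 1 is easily matched and says little. The splits were not compared on the 1571 genes with an unadjusted p under 0.05 by limma. For LbNOX after water the real count was 0 by limma (440 at an unadjusted p under 0.05; 0 by edgeR and 19 by DESeq2), which all 100 of 100 splits reach by necessity, so this count says nothing about chance. The split of M1, M2, M3 and M8 from the rest called 414 genes there, which points to a structure of the samples other than the groups. After ethanol 1 of 10 splits, the real grouping, called 822, too few splits to tell.

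The ethanol response of luciferase livers that was not called in LbNOX livers has 3 technical explanations tested here. Depth is argued against, since 973 luciferase genes and 195 for the difference were still called with all libraries thinned to 10.6 M reads. A like response hidden by spread is argued against for the genes that rose, taken as a set. Their median was 0.0542 in LbNOX livers, 5.41% of that in luciferase livers, and at most 0.0902 with any LbNOX library left out. For the genes that fell the share was 13.3%. Both sets were chosen by their luciferase values, which raises the size of the luciferase medians and lowers these shares. A median also does not exclude a like response of part of the genes. Cell shares are argued against as the whole cause. The ChREBP difference was −1.51 with non-hepatocyte markers as a covariate, 86.9% of its value (72.1% to 96.3% with a library left out). The share set beforehand for arguing against was met with all libraries, but not by the lowest of these. The hepatocyte list, added after the ChREBP result was seen, differed by −0.45, 26.1% of the ChREBP difference. The covariate raised the calls from 1 to 81 in LbNOX livers and from 227 to 305 for the difference. With it 28 genes were called in both constructs in the same direction, so cell shares may hide part of the LbNOX response. A response that depends on NADH oxidation by LbNOX is left open by these tests, as are other effects of the construct.

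The lower interferon-response genes in luciferase livers after ethanol could rest on few libraries or on fewer immune cells. Without M4 the median was −1.14, 77.4% of its value, and camera still called the list at its preset correlation (adjusted p = 4.28e-07), while with all libraries the list had an adjusted p = 0.417 with an estimated correlation. Only water libraries were left out in this test. After ethanol the list level was −1.44 in M10, −0.63 in M11 and −0.27 in M12, as medians of centred log2 values. With T, NK and Kupffer cell markers as a covariate it was −1.20, 81.4% of its value, but 34.0% to 98.2% with a library left out. The share written for arguing against 1 water library, after results were seen, was met without M4. The margin was smaller than the SD of 0.286 between the medians with a water library left out, so no verdict was drawn. Neither test could tell, and a part played by few libraries or by fewer immune cells may remain.

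A sample far from the others of its group was seen in 22 of 268 groups of values, where chance gives about 1 in 20, or 13.4. M1 had the most recovered reads (23.7 M). On lists, as medians of centred log2 values, M8 stood apart for lipogenesis (−0.45), fatty acid oxidation (−0.12), clock (−0.41), pericentral hepatocyte (−0.13), Kupffer (0.54) and endothelial genes (0.81), M3 for endothelial genes (0.80) and M4 for B and plasma cells (1.86). M15, in a group of 3 that was not tested for this, had a like profile (endothelial 0.70, Kupffer 0.55, stellate 0.40); its mean of non-hepatocyte markers was 0.579, against 0.584 in M8 and 0.744 in M3, and its first principal component was 50.2, against 50.7 and 57.8. As log2 of the normalized count plus 1, M8 stood apart for Cyp2e1 (14.41), Irf1 (10.24), Rgs16 (8.05), Tha1 (5.99) and Zbtb16 (8.52). M3 did so for Cd274 (8.35), G6pc (10.01), Ifi47 (11.04) and Tarsl2 (8.34), M4 for Cdc20 (8.95) and Ifit1 (11.59), M1 for Insig1 (10.98) and M6 for Gckr (4.90).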

How the results depend on the processing

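The alternatives on recovered reads and without M3 and M8 were chosen after results were seen. No named gene turned direction under any setting where it was called in the test used or in the alternative. Sign changes of values called in neither were not counted. No paired analysis was possible because the columns carry no replicate number. For each change below the cause was not tested.

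Genes called for ethanol in luciferase livers, 1052 in the test used, were 611 with only the groups compared, 1646 by DESeq2, and 467 (M10) to 1216 (M4) with a library left out, 636 without M12. In LbNOX livers, 1 became 0 without the trend, 2 with only the groups compared, 291 by DESeq2, 116 without M3 and M8, and 0 (M1) to 28 (M14) with a library left out. For LbNOX after water, 0 became 19 by DESeq2, 2 without M3 and M8, and 0 to 1 (M8, M10). After ethanol, 822 became 1365 by DESeq2 and 316 (M10) to 940 (M3), with 320 (M15), 355 (M12) and 400 (M13). For the difference, 227 became 151 without the trend, 644 by DESeq2, 382 without M3 and M8, and 70 (M15) to 402 (M8). Genes called in both constructs, 0 in the test used, were 71 by DESeq2, 24 without M3 and M8, and 0 to 7 (M14), with 1 without M3; with non-hepatocyte markers as a covariate they were 28, and the LbNOX ethanol calls 81.

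Lists called with an estimated correlation were 0 for each comparison but LbNOX after water, which had 1; fry called 12, 0, 1, 4 and 4. In LbNOX livers 8 lists became 16 without M3 and M8 and 4 (M9) to 16 (M8) with a library left out. After water 13 became 8 (M3) to 20 (M8). After ethanol 14 became 8 with quantile normalization and 7 (M10) to 16 (M3), with 8 (M11) and 9 (M15). For the difference 19 became 12 (M15) to 23 (M4), and of the response lists 15 became 0 with an estimated correlation and 4 by fry. The hepatocyte list after water went from −0.13 (M9) to 0.20 (M8, camera adjusted p = 0.0321, a reversal). With quantile normalization the median of all genes was at most 0.0190 from 0. Depth limits genes near the lower end, where levels of a few counts give uncertain folds.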

Other observations

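The tests of zeros were set before their results were seen; the pancreatic genes and the genes called under alternatives were looked at afterwards. The clock list differed between the constructs in its ethanol effect (median −0.39, camera adjusted p = 0.0385; adjusted p = 0.568 with an estimated correlation). M15 carried much of this: the LbNOX ethanol clock level was −0.73 in M15, −0.11 in M13 and 0.03 in M14, and without M15 the median was −0.19 (camera adjusted p = 0.161). Hlf, a gene of this list, rose in luciferase livers (1.24, limma adjusted p = 0.00130) and differed between the constructs (−1.58, adjusted p = 0.0123). Its difference kept the call in all 15 fits with a library left out. Of the list's other genes, 3 picked after their values were seen had fold changes of the same sign in both constructs. None of these 3 was called in LbNOX livers, and likeness was not tested. The clock transcription factor Npas2 had a log2 fold change of 2.92 after ethanol in luciferase livers (adjusted p = 0.0113; 0.0913 without M10) and 3.63 in LbNOX livers (adjusted p = 0.0716). Dbp, a clock output gene, stood at −1.90 (adjusted p = 0.0278; 0.165 without M10) and −1.78 (adjusted p = 0.182), and the clock repressor Nr1d2 at −0.51 (adjusted p = 0.0244; 0.0998 without M12) and −0.56 (adjusted p = 0.127). Without M3 and M8, 14 genes were higher and 10 lower in both constructs, where 2.62 and 1.53 were expected by chance, with Npas2 among them, and 3 went opposite ways; this setting keeps M15, whose markers resemble those of M3 and M8. By DESeq2 32 were higher and 39 lower, with 8.43 and 8.84 expected, and 4 went opposite ways, and Npas2, Dbp and Nr1d2 were among them.

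Genes of digestive enzymes of the pancreas were highest in M8 and M3. Cela2a had 1011 normalized counts in M8 and 117 in M3, and Prss2 had 898 and 120; these were chosen after their values were seen.

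A value of 0 was listed for 86 genes in libraries where the median of the other libraries was at least 100, with 209 such zeros in all and 7 to 22 per library. Of these genes 37 had it in 1 library and 49 in more, up to 8. Poisson counting of reads gave 1.14e-30 such zeros. That outcome followed from choosing genes with a median of at least 100 in the other libraries. Replicates also spread more than Poisson counting allows. The value says only that read counting at the level of the other libraries does not give these zeros. Division of reads among annotated transcripts predicted a higher share of such zeros among genes with more transcripts. Such a 0 was seen in 1.37% of genes with 5 or more transcripts (52 of 3800). The share was 1.95% of genes with 1 transcript (10 of 513, Fisher exact test p = 0.320), so the prediction was not met. Of the 86 genes, 11 had pseudogene or Gm names, and these were not set apart in the test. The test therefore cannot tell whether reads were divided among transcripts. No biological explanation was tested.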
